A study of Drosophila melanogaster with 37 samples.

How the data were processed

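ChIP-seq was done in S2 cells, a male line of Drosophila melanogaster, with antibodies against CLAMP, GAF (the GAGA factor, encoded by trl) and MSL3. Cells had been treated with 4.5 ug/mL of dsRNA against GFP (the control), GAF or CLAMP. Per the labels, chromatin was crosslinked with formaldehyde and sonicated before precipitation, and reads were processed with Bowtie (version not given) and MACS2 2.1.1 on build dm3. The options of MACS2 and the control it was given are not stated in the sources used here. Of the 37 samples, 25 have a deposited peak list. The other 12 are inputs, and reads of inputs were not analysed here. The lists hold regions and no read counts, so the depth of each library is unknown.

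The authors called peaks separately in each library. In the deposited lists, each region carries its fold enrichment (a ratio) as MACS2 gave it for that library. Each region in the deposited lists also carries a −log10 p and a −log10 q for its own library. Both grow with sequencing depth, so fold enrichment, p and q were used mainly to order or select regions within a list. The highest −log10 p of MSL3 libraries and peak numbers at a limit of q were also compared between libraries. Those comparisons depend on the unknown depth. Lists of CLAMP and GAF are narrow peaks whose lowest −log10 p is 1.3. MSL3 lists are broad regions whose lowest −log10 p is 1.0.

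The groups, the 6 comparisons, the measures and tests per comparison, the control comparisons, a set of alternatives and the rule for naming sites were chosen before the data were examined. The analyses of the strongest MSL3 regions, of the composition of lost and gained sites, of weak calls, and of CLAMP sites called after CLAMP RNAi were added afterwards, as were the alternatives named so in the closing section. Each RNAi was compared with GFP RNAi within an antibody. A library was the unit of replication.

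Regions on the arms 2L, 2R, 3L, 3R, 4 and X were used. The other sequences of dm3 hold 1.50% of all regions and were kept for an alternative. Regions of libraries that shared at least 1 bp were merged. Reference sites of an antibody are merged regions called in at least 2 of its libraries over all RNAi conditions, and control sites are those called in at least 2 control libraries. Per library, the measures were the log2 number of peaks, the percentage of peaks on X, the percentage of reference sites recovered, and the recovery on X minus that on autosomes. For MSL3 the Mb covered on X and the percentage of covered bases on X were added. For CLAMP and GAF, recovery at sites shared with the control sites of the other factor minus recovery at the remaining sites was added. Lost sites were called in every control library and in no library of the RNAi, and gained sites were the converse.

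Means over libraries were compared with exact two-sided permutation tests. With 3 against 2 libraries the smallest p possible is 0.2, with 3 against 3 it is 0.1, and with 4 against 3 it is 0.0571, so no comparison between RNAi conditions could pass 0.05. Adjusted p values are Benjamini-Hochberg values over the family of tests named with them. Overlaps of sites were set against 1000 circular shifts of 1 of the sets along each arm, for which the smallest p possible is 0.000999, 1-sided. Counts of sites were compared with two-sided Fisher's exact tests. Sites are not independent replicates, so these tests describe the site sets and not variation between cultures. Confidence intervals of percentages are exact Clopper-Pearson 95% intervals and cover counting error only.

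The lists differ in length by large factors, and a longer list recovers more sites. Equal-length lists were therefore formed from each library's regions of highest −log10 q (ties by −log10 p, then fold enrichment), as many as the shortest list of the comparison holds. The strongest MSL3 regions are the top 103 of each library, because the shortest MSL3 list has 103. The other alternatives were a −log10 q of at least 5, all sequences, an overlap of 50% of the shorter region, sites called in every control library, reference sites from control libraries, the replicate number as a block, and leaving out each library in turn. A limit of q at 0.05 was added later.

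Sites were named by a rule. It takes the 10 control sites per antibody with the best mean rank of fold enrichment within the control lists, and the 5 lost and the 5 gained sites per comparison with the best mean rank in the libraries that call them. Coordinates are 1-based on dm3. The gene table at hand belongs to Release 6 of the genome and no dm3 sequence or annotation was at hand, so no genes are named. The planned searches for GA repeats and for gene features were left out for the same reason.

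Computations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Overlap counting was checked on simulated data against a direct count for 2400 regions, with 0 disagreements. Lists were also simulated with independent calls, drawn at each library's recovery of the reference sites. Seeded lost sites were set as called in every control list and in no list of the RNAi. That 200 of 200 were found in each comparison was therefore fixed beforehand and checks only the counting. Unseeded lost sites in these simulated lists were not taken as the number to expect without a change. Under CLAMP RNAi they were 712 for CLAMP, 235 for GAF and 38 for MSL3, against 1059, 11 and 56 in the deposited lists, and under GAF RNAi 37, 75 and 1 against 15, 51 and 0. Of 20 pairs of independent site sets, 1 gave a shift p below 0.05.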

Results

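Occupancy of CLAMP, GAF and MSL3 was mapped in male S2 cells to place the 2 GA-binding factors relative to each other and to the MSL complex. CLAMP is a zinc-finger protein that binds GA-rich DNA and is needed for recruitment of the MSL complex to the male X chromosome. GAF binds related GAGA sequences at many promoters, and MSL3 is a subunit of the MSL dosage compensation complex. Under GFP RNAi, peak lists were present for 3 libraries of CLAMP, 3 of GAF and 4 of MSL3. Under GAF RNAi there were 2, 2 and 3, and under CLAMP RNAi 2, 3 and 3 libraries of these antibodies. On the 6 arms a CLAMP list held 430 to 10984 peaks, a GAF list 2676 to 29233 and an MSL3 list 103 to 33316. Read depth behind these calls is unknown.

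**Figure D1:**
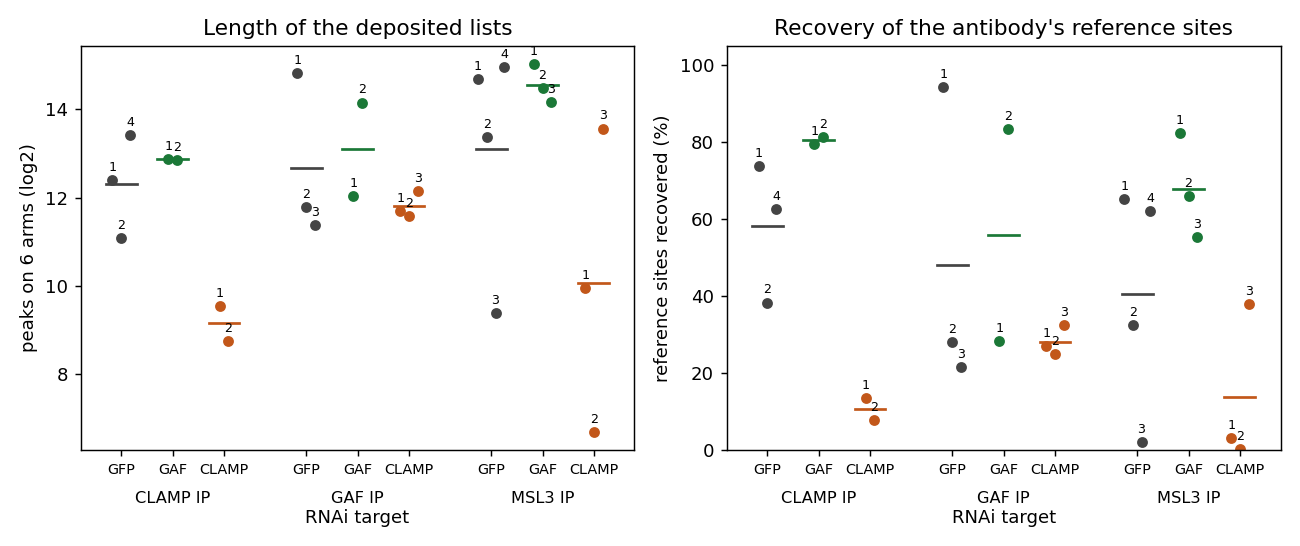
Left, the number of peaks on the 6 arms per library (log2 axis); right, the percentage of the antibody's reference sites each library recovered. Points are libraries with their replicate number and lines are group means; both CLAMP lists after CLAMP RNAi (7.91% and 13.6% of sites) lie below the 3 control lists (38.3% to 73.8%).

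In control cells CLAMP and GAF shared a large part of their sites. Of 2751 CLAMP control sites, 1354 (49.2%) overlapped a GAF control site, 16.9 times the mean of the circular shifts (2.91%). Of 3219 GAF control sites, 1334 (41.4%) overlapped a CLAMP site, 16.6 times the mean of the shifts. The X chromosome, which makes up 18.6% of the 6 arms, carried 766 CLAMP sites (27.8%) and 607 GAF sites (18.9%). On X a smaller part of the CLAMP sites was shared with GAF than on autosomes (39.3% against 53.0%), while a larger part of the GAF sites was shared with CLAMP (48.8% against 39.7%). Both overlaps gave the smallest shift p possible, 0.000999. The contrasts between X and autosomes gave Fisher's exact p of 9.3e-11 for CLAMP sites and 5.6e-05 for GAF sites (adjusted over the 2 tests, 1.9e-10 and 5.6e-05).

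The strongest control sites of the 3 antibodies lay in different places. CLAMP had 3 of its 10 top-ranked sites on X, and 4 of the 10 were also GAF sites. Its first-ranked site was at X 1292973 to 1294219, a GAF site as well, followed by 2L 7827691 to 7829331 and 2L 4809998 to 4810594. Of the 10 top-ranked GAF sites, 9 were on X and 4 were CLAMP sites, led by X 18206472 to 18207191 and X 18298399 to 18298964, both shared with CLAMP. All 10 top-ranked MSL3 regions were on X and 9 of them held a CLAMP site, with X 5558216 to 5565781 and X 11471142 to 11478738 at the head. This order rests partly on control replicate 4, where the 10 regions ranked 729 to 3468: the last of them, X 19633804 to 19638044, ranked 14, 8 and 17 in replicates 1 to 3, and the first ranked 57, 21 and 60. The X share of whole lists averaged 19.1% ± 10.6 for CLAMP (SD, n = 3), 14.4% ± 7.26 for GAF (SD, n = 3) and 17.2% ± 17.5 for MSL3 (SD, n = 4), and differences between antibodies were within this spread (exact permutation p 0.6 to 1). The difference between CLAMP and GAF was 4.73 points in whole lists, 11.5 points in equal-length lists and 13.2 points at a −log10 q of at least 5, the latter pair each with an exact permutation p of 0.1, the smallest possible for n = 3 against 3.

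On X, MSL3 regions of control cells covered CLAMP sites that lack GAF more often than those with GAF. It covered 251 of 465 X sites of CLAMP alone (54.0%, 95% interval 49.3 to 58.6), 50 of 301 sites of CLAMP with GAF (16.6%, 12.6 to 21.3) and 27 of 311 sites of GAF alone (8.68%, 5.80 to 12.4). Single control libraries 1 to 3 covered 57.8%, 44.3% and 38.7% of the CLAMP-alone sites and 18.9%, 12.0% and 6.31% of the shared sites, while replicate 4 went the other way with 20.9% and 29.2%. The means of the circular shifts were 13.7%, 14.3% and 13.8% for these classes. On autosomes MSL3 covered 19.3%, 9.31% and 17.2% of the same classes. The coverage of CLAMP-alone sites lay above all shifts (p 0.000999, the smallest possible; adjusted over 3 classes 0.00300) and that of GAF-alone sites lay below most (p 0.00599, adjusted 0.0180). Sites of CLAMP alone exceeded sites of both factors by 37.4 percentage points and sites of GAF alone by 45.3 points (Fisher's exact p 2.2e-26 and 2.6e-42, adjusted over 3 tests 3.2e-26 and 7.8e-42). With only the control sites called in every control library, these differences were 21.4 and 26.1 points. The step from GAF-alone sites to shared sites was 7.93 points (Fisher's exact p 0.00337, adjusted 0.00337). With CLAMP and GAF peaks limited to a −log10 q of at least 5 this step was 6.21 points and no longer passed (p 0.0551).

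**Figure D2:**
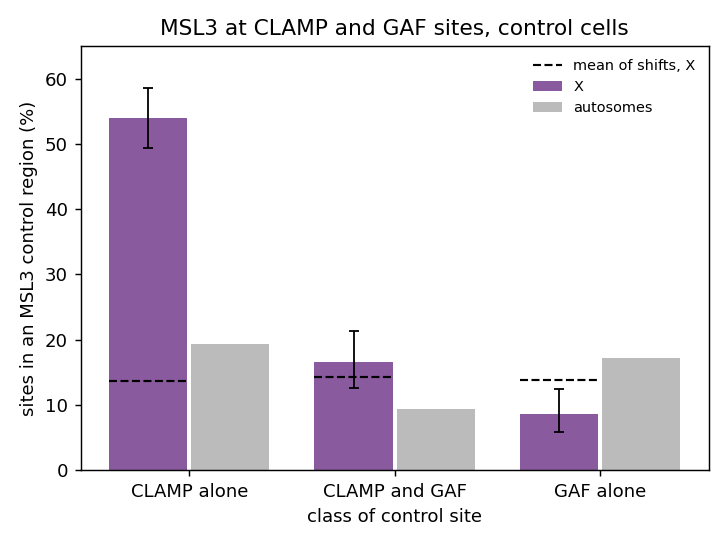
Percentage of CLAMP and GAF control sites that lie in an MSL3 control region, by class of site, on X and on autosomes; bars start at 0, whiskers are exact 95% intervals for X and dashed lines are the mean of 1000 circular shifts on X. CLAMP sites without GAF on X stand at 54.0%, against 16.6% with GAF and 8.68% for GAF alone.

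The strongest MSL3 regions of control cells were almost all CLAMP sites on X. Taking the 103 strongest regions of each control library, 97 regions were among them in at least 2 libraries, 96 of these on X, with a median length of 3775 bp over the 97. Of the 96, 95 held a CLAMP site (99.0%, mean of shifts 13.4%, p 0.000999) and 14 held a GAF site (14.6%, mean of shifts 10.02%, p 0.0879). CLAMP without GAF was present in 81. The set holds the same 97 regions without control MSL3 replicate 4. That library's own 103 strongest regions were 8.74% on X, against 94.2%, 99.0% and 99.0% in replicates 1 to 3, and shared 0 regions with theirs, and the lists do not show whether its label is right or its precipitation worked.

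CLAMP was the target of CLAMP RNAi, and its own lists were short there. The 2 CLAMP libraries held a geometric mean of 567.5 peaks against 5049 in 3 control libraries, 8.90-fold fewer (log2 difference −3.15, and −3.76 without control replicate 2). They recovered 10.7% ± 4.00 of the reference sites (SD, n = 2) against 58.2% ± 18.1 (SD, n = 3). Sites called in every control library and in neither RNAi library numbered 1059, with 335 on X, 528 at GAF sites and 222 in MSL3 regions, and 0 sites were gained. The best-ranked lost sites were 2L 594623 to 595503, X 16985122 to 16985971, X 20920985 to 20921653, X 170057 to 170529 and 2L 9158272 to 9158817. The strongest control sites were still called, since 8 of the 10 top-ranked CLAMP sites appeared in both CLAMP RNAi lists and the other 2 in 1 list. Of all 2751 control sites 26.2% were called in either RNAi library, 31.8% of those shared with GAF and 20.8% of those without GAF (Fisher's exact p 7.1e-11, adjusted over 2 tests 1.4e-10). For X and autosomes these values were 23.8% and 27.2% (Fisher's exact p 0.0736, adjusted 0.0736). The control lists also recovered GAF-shared CLAMP reference sites more often than other CLAMP reference sites, by 28.1, 32.7 and 23.2 points. The contrast between sites with and without GAF therefore need not be an effect of CLAMP RNAi.

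The 2 groups did not overlap in the number of peaks or in recovery, and both exact permutation p values were 0.2, the smallest possible for 3 against 2 libraries (adjusted over 6 comparisons 0.857 and 0.457). With lists of 430 peaks the difference in recovery was −0.629 points (62.3% ± 0.667 against 62.9% ± 2.75, SD, exact permutation p 1, n = 2 and 3), and 14 sites were lost and 25 gained. The reference sites were rebuilt from the cut lists, and 430 peaks are the whole list of CLAMP RNAi replicate 2. A loss of CLAMP across all its sites could therefore not show in this comparison. Without control replicate 2 the lost sites were 1760.

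GAF was the target of GAF RNAi, and its lists in the libraries labelled GAF RNAi lay within the range of the control lists. They held 4220 and 18267 peaks, and the control lists 29233, 3543 and 2676. As geometric means this is 1.35 times as many, a direction that turned without control replicate 2 or 3 or without GAF RNAi replicate 2 (log2 differences −0.0106, −0.213 and −0.628; 1.51 without control replicate 1). Recovery of GAF reference sites was 55.9% ± 38.9 (SD, n = 2) against 48.0% ± 40.1 (SD, n = 3). Of the 2231 sites called in every control library, 1705 were called in both RNAi libraries, all 10 top-ranked GAF sites among them. There were 51 lost sites, 11 of them on X, and 33 gained sites with 1 on X. Of the 10 splits of these libraries into groups of the same sizes, 6, the real one included, gave at least the real 84 lost and gained sites (highest other 6782). Lost sites were led by X 6699575 to 6699904 and 2L 16548101 to 16548480, and gained sites by 2L 12066621 to 12066997 and 2R 13150246 to 13150815. The difference in recovery was within the spread of libraries (exact permutation p 1, smallest possible 0.2, adjusted over 6 comparisons 1). It was negative with equal-length lists (−11.2 points, exact permutation p 0.6). The lost sites were 332 without control replicate 3, 488 without GAF RNAi replicate 1 and 93 without GAF RNAi replicate 2, and the gained sites were 102 without control replicate 1 and 308 without GAF RNAi replicate 2.

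CLAMP lists in the libraries labelled GAF RNAi still called most CLAMP sites of control cells. The GAF lists do not show that GAF was depleted, so this comparison need not test whether CLAMP depends on GAF. The libraries recovered 80.5% ± 1.39 of CLAMP reference sites (SD, n = 2) against 58.2% ± 18.1 in control (SD, n = 3), with 1.48 times as many peaks (log2 difference 0.565, and −0.0413 without control replicate 2). Of the 1745 sites called in every control library, 1574 were called in both RNAi libraries, all 10 top-ranked CLAMP sites among them. The lost sites numbered 15, 11 of them GAF sites and 7 on X, led by X 12440963 to 12441285, X 19247581 to 19247887 and X 1845477 to 1846339, which are all GAF sites. The 577 gained sites lay mostly away from GAF (41 at GAF sites) and from X (41), and 262 of them (45.4%) were on 2L. The best-ranked gained sites were 3R 9883054 to 9883562, 3R 15356785 to 15357214 and 3R 11490436 to 11490933. Across autosomal bins of 1 Mb, which are not independent replicates, the number of gained sites had a Spearman coefficient of 0.614 with that of control MSL3 replicate 3 regions. The gained set held 88 sites at a −log10 q of at least 5 and 87 (with 52 lost) in equal-length lists, and another split of the 5 libraries gave 562 lost and gained sites against the real 592. The exact permutation p of recovery was 0.2, the smallest possible (adjusted over 6 comparisons 0.457), and with reference sites taken from control libraries the difference was −2.45 points. Recovery at GAF-shared minus other CLAMP sites was 5.61 ± 10.8 points (SD, n = 2) against 28.0 ± 4.75 in control (SD, n = 3; difference −22.4, exact permutation p 0.2, adjusted over 2 tests 0.2), and −2.40 points with equal-length lists. Without control replicate 1 the gained sites were 1139, and the lost sites were 165 without control replicate 2, 28 without control replicate 4 and 164 without GAF RNAi replicate 1.

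In equal-length lists, GAF after CLAMP RNAi was called more completely at CLAMP sites, relative to its other sites, than in control cells. With 2676 peaks per list, GAF recovered 91.7%, 89.8% and 93.9% of its sites at CLAMP control sites in the 3 CLAMP RNAi libraries and 86.0%, 82.2% and 79.9% in the 3 control libraries. At its other sites recovery was 77.5%, 76.7% and 84.9% against 82.7%, 80.1% and 81.8%. The difference between the site classes was 12.2 ± 2.77 points after CLAMP RNAi (SD, n = 3) and 1.13 ± 2.71 in control (SD, n = 3). Between sites on X and on autosomes it was 1.94 ± 1.36 points after CLAMP RNAi and −5.25 ± 3.01 in control. Neither pair of groups overlapped, which chance gives in 10% of such designs, and each exact permutation p was 0.1, the smallest possible with n = 3 (adjusted over 20 equal-length tests 0.5). In whole lists these contrasts were 32.0 and 22.7 points higher than in control (exact permutation p 0.1, adjusted 0.2 over 2 tests and 0.6 over 6). Without control replicate 1, whose list is the longest, they were 4.58 and 7.01 points. The exact permutation p were then 0.6 and 0.2, where 0.2 is the smallest possible for 3 against 2 libraries. The size of the whole-list contrast at CLAMP sites thus rested largely on that library.

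**Figure D3:**
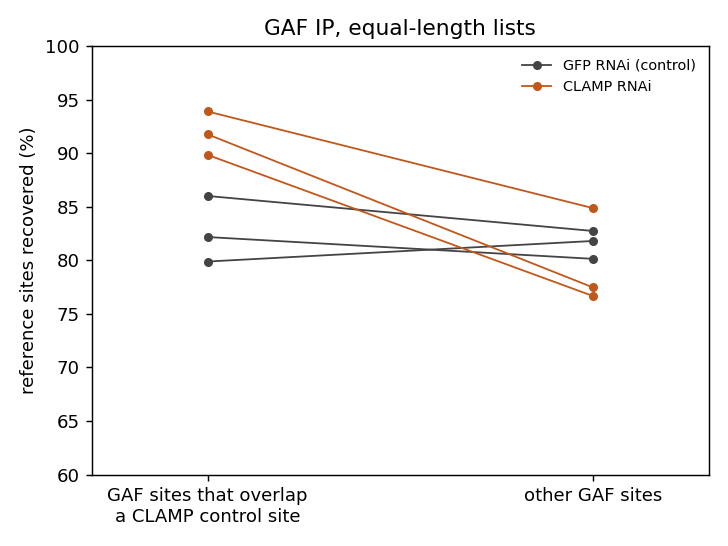
Percentage of GAF reference sites recovered by each GAF library, at sites that overlap a CLAMP control site and at other sites, with 2676 peaks per list; the vertical axis does not start at 0. Each line is a library, and the 3 CLAMP RNAi libraries lie at 89.8% to 93.9% at CLAMP sites, above the 3 control libraries (79.9% to 86.0%).

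GAF gained 95 sites after CLAMP RNAi and lost 11. Of the gained sites 61 were CLAMP control sites (64.2%), 46 were on X (48.4%) and 26 lay in MSL3 regions (27.4%). The best-ranked gained sites were 2L 5191 to 6175, X 12543558 to 12544350, X 10118663 to 10119137, X 9560394 to 9560992 and X 13699484 to 13700173, all CLAMP sites, and the X sites at 12543558, 10118663 and 9560394 lay in MSL3 regions. Of the 11 lost sites 6 were CLAMP control sites (54.5%), 2 were on X (18.2%) and 6 lay in MSL3 regions (54.5%). Lost and gained sites were not tested against each other. Among the lost sites was X 1292959 to 1293519, which lies at the first-ranked CLAMP site. The other 2482 GAF sites called in all 3 CLAMP RNAi libraries were at CLAMP sites in 49.6%, on X in 20.1% and in MSL3 regions in 12.6%. Fisher's exact p against the gained sites were 0.00629, 1.6e-09 and 0.000142 (adjusted over 5 tests 0.00629, 2.7e-09 and 0.000178). GAF libraries labelled GAF RNAi called 17 and 7 of the 95. Of the 2231 sites called in every control library, 2106 were called in all 3 CLAMP RNAi libraries, all 10 top-ranked GAF sites among them. Without control replicate 1 the gained sites were 171, with 63.2% at CLAMP sites and 39.2% on X, and without CLAMP RNAi replicate 2 they were 154, with 53.2% and 41.6%. At a −log10 q of at least 5 there were 30 gained and 0 lost sites, and equal-length lists gave 124 gained and 47 lost. The lost sites were 310 without control replicate 3, and 20 and 23 without CLAMP RNAi replicates 1 and 3.

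MSL3 after CLAMP RNAi, the comparison that asks whether the MSL complex depends on CLAMP, was called at fewer of its strong X regions. The 96 strongest X regions of control cells were called to 28.1%, 12.5% and 71.9% in the 3 CLAMP RNAi libraries and to 100%, 96.9%, 100% and 53.1% in the 4 control libraries (means 37.5% ± 30.8, SD, n = 3, and 87.5% ± 23.0, SD, n = 4). X sites of CLAMP alone were covered to 10.04% ± 10.4 (SD, n = 3) against 40.4% ± 15.3 (SD, n = 4). Autosomal sites of CLAMP alone were covered to 0.751%, 0% and 10.7% against 20.3%, 4.72%, 0.215% and 36.9%, so low values were not confined to X. In whole lists, recovery on X minus that on autosomes was 0.363 ± 1.24 points against 5.07 ± 15.4 (SD). The difference was −4.71 points (exact permutation p 0.743, adjusted over 6 comparisons 0.743), which shows no loss particular to X. Of the 103 strongest regions of each CLAMP RNAi library, 26.2%, 40.8% and 23.3% were on X, against 94.2%, 99.0%, 99.0% and 8.74% in control. In the CLAMP RNAi libraries nearly none of these regions passed q of 0.05. The highest −log10 q was 0.0919 in replicate 1 and 0 in replicate 2, whose 103 regions are its whole list. Replicate 3 had 1 region with q below 0.05, and control replicates 1 to 4 had 143, 6, 0 and 4. Among the 10 top-ranked MSL3 regions 2 were called in all 3 CLAMP RNAi libraries, 3 in 2 libraries and 5 in 1 library. There were 56 lost regions, 34 on X and 31 at CLAMP sites, and 0 gained regions, while equal-length lists without control replicate 4 gave 47 lost and 6 gained. The best-ranked lost regions were X 1407224 to 1411919, X 10490269 to 10493684, 3L 4725053 to 4732161, X 1372884 to 1377187 and X 18682235 to 18686636.

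Since the 96 regions were picked from control lists, calls were also counted in regions picked without the control library tested, and were then 39.3% ± 31.4 after CLAMP RNAi (SD, n = 3) and 87.3% ± 22.8 in control (SD, n = 4; exact permutation p 0.114). In equal-length lists, recovery of the 129 X sites minus that of the 30 autosomal sites was −32.5 ± 14.2 points after CLAMP RNAi and 48.4 ± 32.9 in control, and the groups did not overlap (difference −80.9, exact permutation p 0.0571, the smallest possible with n = 3 and 4, adjusted over 20 tests 0.5). Control replicate 4 recovered 0% of both classes there. The sites were merged from these same lists of 103 regions, so the contrast partly restates their X shares and is no separate support. GAF RNAi replicate 3 stood at −22.4 points, below CLAMP RNAi replicate 3 at −16.0. None of these MSL3 differences passed a test. Exact permutation p was 0.114 for calls of strong X regions, 0.114 for X sites of CLAMP alone and 0.229 for the X share of the 103 strongest regions with n = 4 and 3, where the smallest possible is 0.0571 (adjusted over 6 tests 0.343, 0.343 and 0.457). Without control replicate 4 the differences were −61.5, −36.9 and −67.3 points, each with an exact permutation p of 0.1, the smallest possible for n = 3 against 3. Lists were 8.18-fold shorter after CLAMP RNAi as geometric means (1071 and 8761 regions, log2 difference −3.03, exact permutation p 0.286 with n = 3 and 4, adjusted over 6 comparisons 0.857). The log2 difference was −1.34 without CLAMP RNAi replicate 2 and −4.78 without replicate 3, and the X share of whole lists was 19.4% ± 18.6 against 17.2% ± 17.5. The lost regions were 1683 without control replicate 3, 96 without control replicate 4 and 220 without CLAMP RNAi replicate 3.

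**Figure D4:**
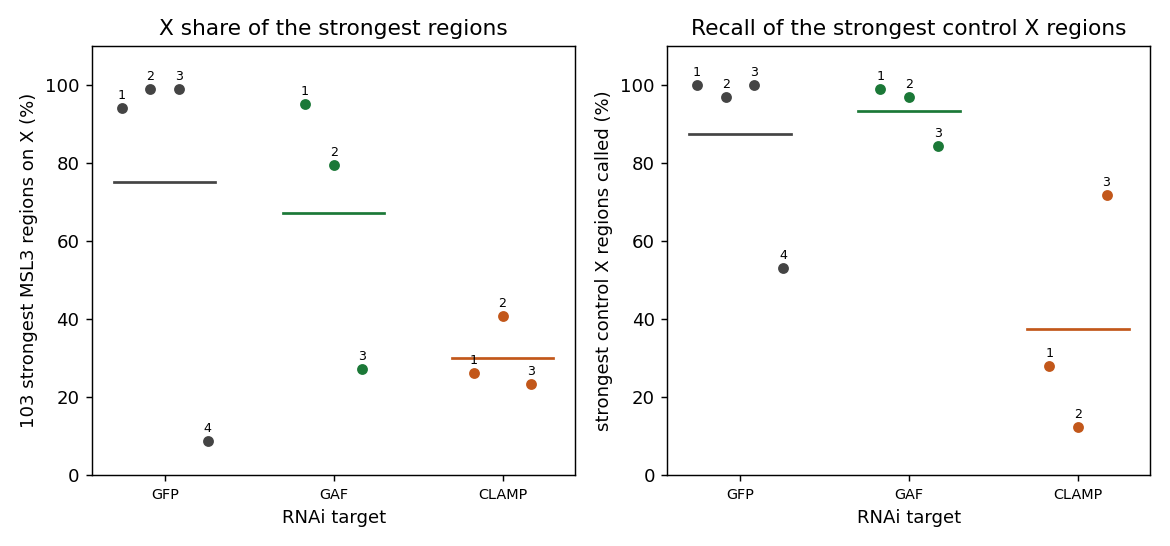
Left, the percentage of each MSL3 library's 103 strongest regions that is on X; right, the percentage of the 96 strongest control X regions that each MSL3 library called. Points are libraries with their replicate number and lines are group means; CLAMP RNAi libraries lie at 23.3% to 40.8% on the left, control replicates 1 to 3 at 94.2% to 99.0% and control replicate 4 at 8.74%.

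MSL3 in the libraries labelled GAF RNAi was still called at its strong X regions. Here too the lists do not show that GAF was depleted. The 96 strongest control X regions were called to 93.4% ± 7.89 (SD, n = 3) against 87.5% ± 23.0 in control (SD, n = 4). X sites of CLAMP alone were covered to 40.9% ± 19.1 against 40.4% ± 15.3, and all 10 top-ranked MSL3 regions were called in all 3 libraries. X shares of the 103 strongest regions were 95.1%, 79.6% and 27.2%, so replicate 3 stood in the range of the CLAMP RNAi libraries. There were 0 lost regions and 416 gained ones, of which 7 were on X, led by 2R 7588159 to 7589361 and 3L 21784409 to 21785050. Equal-length lists gave 0 gained regions, with or without control replicate 4 (0 lost with it and 4 without), and 9 of the 35 splits of the libraries gave as many lost and gained regions as the real one. Lists held 2.76 times as many regions as in control (log2 difference 1.46, exact permutation p 0.457 with n = 3 and 4, adjusted over 6 comparisons 0.914), and the log2 difference was 0.227 without control replicate 3. The X share of whole lists was 6.30% ± 0.952 against 17.2% ± 17.5 (SD, exact permutation p 0.114, adjusted over 6 comparisons 0.686). The share of covered bases on X was 7.91% ± 2.80 against 27.9% ± 28.7 (SD, exact permutation p 0.114, adjusted over 2 tests 0.229). Without control replicate 3 these 2 differences were −2.15 and −6.01 points. Exact permutation p for calls of strong X regions and for X sites of CLAMP alone was 1, and for the X share of the strongest regions it was 0.8, with adjusted values of 1. Without control replicate 4 these differences were −5.56, −6.09 and −30.1 points (exact permutation p 0.3, 0.8 and 0.2). The gained regions were 1231 and 991 without control replicates 1 and 4, and 714, 1425 and 1850 without GAF RNAi replicates 1, 2 and 3, and without control replicate 3 the lost regions were 18.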

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

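The X share of MSL3 in equal-length lists was planned, and so were the rules that picked out the libraries and sequences named here; the other tests in this part were chosen only after the result was seen.

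Control MSL3 replicate 3 lay far from the other 3 control MSL3 libraries in the X share of its whole list, 43.4% against 6.72%, 9.37% and 9.23%. Its list of 668 regions was the shortest of the 4. Cut to their 668 strongest regions, control replicates 1 and 2 had X shares of 44.6% and 59.9%, and replicate 4 had 6.74%. The distance of replicate 3 from replicates 1 and 2 was thus absent at equal length. Control MSL3 replicate 4 lay far from the others in the X share of its 103 strongest regions, 8.74% against 94.2% to 99.0%. It was also the only MSL3 library with mitochondrial regions, 7 in number. The lists do not show whether its antibody label is right or its precipitation worked, and every control mean of MSL3 that includes it carries this doubt. In all, 11 measures were examined over these 4 libraries, and chance picks out about 1 in 20 such groups.

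The mean share of peaks on sequences outside the 6 arms was above the highest control library in 3 groups. The means were 1.87% for GAF after GAF RNAi (exact permutation p 0.2, n = 2 and 3), 0.946% for GAF after CLAMP RNAi (exact permutation p 0.9, n = 3 and 3) and 5.24% for MSL3 after CLAMP RNAi (exact permutation p 0.171, n = 3 and 4). The highest control libraries stood at 0.361%, 0.361% and 3.33%. A single library carries the means after CLAMP RNAi: the GAF libraries stood at 0.0602%, 0.0327% and 2.75%, and the MSL3 libraries at 2.96%, 9.65% (11 of 114 regions) and 3.11%. The GAF libraries under GAF RNAi stood at 3.21% and 0.523%.

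The X share of the 103 strongest MSL3 regions averaged 30.1% after CLAMP RNAi and 75.2% in control cells, or 97.4% without control replicate 4. Of the strong X regions that CLAMP RNAi libraries did have, at least 55.6% per library lay at the strongest control regions, above the highest shift in each. This overlap cannot decide whether MSL3 was precipitated. Regions that any antibody precipitates could give it too, and reads of inputs were not analysed here. Weaker lists stay open. The CLAMP RNAi libraries differed by −67.3 points from the 3 controls whose highest −log10 p lies within their range (2.45 to 16.8). But 2 of the 3 CLAMP RNAi libraries were weaker than every other MSL3 library (lowest 4.31), and control replicate 4 lay just outside the range at 18.1. GAF RNAi replicates 2 and 3 lay within the range (10.1 and 5.27) and had X shares of 79.6% and 27.2%. A less efficient precipitation cannot be told apart from an effect of CLAMP RNAi, since libraries without CLAMP RNAi had X shares of 27.2% and 8.74%, and the lists record no measure of efficiency. A loss of MSL3 from strong X regions with less CLAMP may therefore be part of the pattern, as a hypothesis that these libraries leave open.

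Regions lost and gained by MSL3 were also counted over all splits of the libraries into groups of the same sizes. After CLAMP RNAi 8 of 35 splits gave as many as the real 56 (highest other 2877), and after GAF RNAi 9 of 35 gave as many as the real 416 (highest other 1705), so chance is not excluded for either count. The highest splits exceed the real counts several times over, and what their libraries share was not tested. For GAF after CLAMP RNAi 1 of the 10 splits, the real one, gave 106 sites and the highest other gave 69, and 10 splits are too few for a share under 0.05.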

How the results depend on the processing

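The limit of q at 0.05, equal-length recovery on X, equal-length X shares between antibodies, every value without control MSL3 replicate 4 in equal-length lists, and the leave-one-out and held-out values of the strongest MSL3 regions, of X sites of CLAMP alone and of the makeup of gained GAF sites were tests chosen only after the result was seen.

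Of the values recomputed under alternatives, 464 kept their direction, their side of 0.05 and, for counts, a size within 1.5 times; 56 counts moved further, 44 values reversed and 1 became weaker. No comparison between RNAi conditions could pass 0.05 under any setting, so keeping its side of the threshold says nothing about its stability there. The overlap of CLAMP and GAF sites kept its direction and the smallest p possible in every setting run, from 40.6% to 53.0% of CLAMP sites and from 29.5% to 45.8% of GAF sites. MSL3 coverage of X sites of CLAMP alone exceeded that of shared sites by 21.4 to 42.4 points and that of GAF-alone sites by 26.1 to 49.8 points, always past the threshold. Its step from GAF-alone to shared sites was 6.21 points with a −log10 q of at least 5 and then no longer passed, and 4.73 to 8.65 points elsewhere. Read depth is unknown, and it limits what the counts of lost and gained sites can show, since the length of a list depends on it.

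At a −log10 q of at least 5 the sites lost and gained were 1 and 4 for GAF under GAF RNAi, 1 and 88 for CLAMP under GAF RNAi, and 0 and 30 for GAF under CLAMP RNAi, and 435 were lost for CLAMP under CLAMP RNAi. Fewer peaks enter at that limit. Recovery for GAF under CLAMP RNAi then reversed to 0.598 points. At q below 0.05 the lost and gained sites were 22 and 13 for GAF under GAF RNAi and 5 and 201 for CLAMP under GAF RNAi, 2 were lost for GAF under CLAMP RNAi, and the X share of CLAMP peaks under CLAMP RNAi reversed to −1.08 points.

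With equal-length lists, where length cannot differ, the lost and gained sites were 14 and 25 for CLAMP under CLAMP RNAi and 52 and 87 for CLAMP under GAF RNAi. For MSL3 under CLAMP RNAi they were 0 and 6, the 0 fixed beforehand because control replicate 4 calls none of the strongest regions of the other controls. There were 13 gained for GAF under GAF RNAi, 47 lost for GAF under CLAMP RNAi and 0 gained for MSL3 under GAF RNAi. Recovery reversed to −11.2 points for GAF under GAF RNAi and to 3.35 points for GAF under CLAMP RNAi. The X share reversed to −2.36 points for CLAMP under CLAMP RNAi, to −45.1 points for MSL3 under CLAMP RNAi (−67.3 without control replicate 4) and to −9.12 points for CLAMP minus MSL3 in control cells. Without control replicate 4, equal-length MSL3 lists gave 4 lost, 0 gained and a recovery of −10.0 points under GAF RNAi, and 47 lost, 6 gained and a recovery of −39.8 points under CLAMP RNAi. Recovery on X minus autosomes in equal-length lists kept its direction in all 6 comparisons. With strong X regions picked without the control library tested, the difference in calls was −48.0 points under CLAMP RNAi and 8.07 under GAF RNAi. With reference sites from control libraries, recovery reversed to −16.4 points for GAF and −2.45 points for CLAMP under GAF RNAi, since sites called only under RNAi no longer count. Except where a clause says so, the cause was not tested.

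With the replicate number as a replicate block, 3 differences reversed: the log2 number of GAF peaks under GAF RNAi (−0.213), GAF recovery under GAF RNAi (−5.24 points) and the X share of MSL3 regions under CLAMP RNAi (−0.466 points). Deviations of same-numbered libraries did not correlate in common (for GAF under GAF RNAi −0.763 and −0.602), so the numbers were not taken to pair the libraries. The cause was not tested.

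Leaving out 1 library at a time gave these ranges. For GAF under GAF RNAi, log2 peak number ranged from −0.628 to 1.51, recovery from −5.24 to 36.8 points, lost sites from 61 to 488 and gained from 25 to 308. For CLAMP under CLAMP RNAi, log2 peak number ranged from −3.76 to −2.59, lost sites from 1075 to 1760 and gained from 0 to 1. For CLAMP under GAF RNAi, log2 peak number ranged from −0.0413 to 1.13, lost sites from 16 to 165 and gained from 0 to 1139. That 0 arises when 1 GAF RNAi library is left, since the call in another library that a site needs could then come only from the short CLAMP RNAi lists, and it says nothing about stability; without 1 control library the gained sites were 579 to 1139. For GAF under CLAMP RNAi, log2 peak number ranged from −1.50 to 0.223, recovery from −33.0 to 11.2 points, lost sites from 11 to 310, gained from 107 to 171, and gained at CLAMP sites from 65 to 108. For MSL3 under GAF RNAi, log2 region number ranged from 0.227 to 2.08, lost regions from 0 to 18, gained from 416 to 1850, calls of strong X regions from −5.56 to 10.4 points, X share of the strongest from −30.1 to 12.1 points (0 without control replicate 2 or 3) and X sites of CLAMP alone from −7.96 to 10.9 points. For MSL3 under CLAMP RNAi, log2 region number ranged from −4.78 to −1.34, X share from −8.52 to 10.9 points, share of covered bases on X from −14.8 to 10.9 points, lost regions from 56 to 1683 and gained from 0 to 1, while calls of strong X regions (−67.2 to −37.5), X share of the strongest (−67.3 to −37.2) and X sites of CLAMP alone (−36.9 to −24.6) stayed negative. X shares in control cells ranged from −0.749 to 9.79 points for CLAMP minus GAF, −3.53 to 10.7 for CLAMP minus MSL3 and −6.27 to 5.96 for GAF minus MSL3. The cause was not tested.

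Not run were a −log10 q of at least 5 for MSL3, whose lists are then empty in several libraries, and for the peak number and X share of CLAMP under CLAMP RNAi, where replicate 2 has 0 peaks. The alternatives for GA repeats, for the summit window and for the distance to promoters were not run either, for want of a dm3 sequence and annotation.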

Other observations

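The equal-length contrast of GAF recovery was planned and the test of regions that any antibody precipitates was set before its result; the other tests in this part were chosen only after the result was seen.

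MSL3 was also called widely outside X, but nearly all of its calls were weak. Of its 14324 control regions 1021 (7.13%) were on X, a smaller share than the arm's 18.6% of the sequence, while its strongest regions were on X. In control replicates 1 to 4, 143 of 26306, 6 of 10572, 0 of 668 and 4 of 31717 regions had q below 0.05. Of these, 95.8% were on X in replicate 1, 100% in replicate 2 and 0% in replicate 4. The whole-list share therefore does not show wide MSL3 binding outside X. CLAMP sites in X regions of MSL3 were called after CLAMP RNAi in 26.9% of 301. All CLAMP sites on X were called in 23.8% of 766 and CLAMP sites in general in 26.2% of 2751, and the difference was not tested. Among libraries with the same replicate number, CLAMP had 0.155 and 0.522 times as many peaks at q below 0.05 as GAF in control cells, 1.38 and 0.197 times as many under GAF RNAi, and 0.138 and 0.0298 times as many under CLAMP RNAi. At a −log10 q of at least 5 these ratios were 0.498 and 0.311, 1.06 and 0.285, and 0.0821 and 0, so the order of the control replicates turned. Control MSL3 replicate 3 listed 0 regions on 2R, and CLAMP RNAi MSL3 replicate 2 listed 0 on 3R.

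GAF sites gained after CLAMP RNAi lay at CLAMP control sites in 64.2%, against 26.7% of the 217 sites that separated the groups in the other splits of the same 6 libraries (Fisher's exact p 6.2e-10, adjusted over 5 tests 1.5e-09). The 11 sites lost after CLAMP RNAi lay there in 54.5%, so a place at a CLAMP site was not particular to gained sites. List length as the whole cause is argued against by equal-length lists, where GAF recovery at CLAMP sites relative to its other sites was still 11.0 points higher after CLAMP RNAi, with no overlap between 3 and 3 libraries. Regions that any antibody precipitates stay open: CLAMP lists of CLAMP RNAi called 32.8% of the gained GAF sites at CLAMP sites and 34.2% of the other 1230 GAF sites at CLAMP sites (Fisher's exact p 0.890), which decides nothing either way. A candidate explanation is that GAF enters sites that CLAMP has left, a hypothesis found and tested on the same data. The calls in CLAMP lists of CLAMP RNAi (32.8% and 34.2%) show no greater loss of CLAMP at the gained sites than at the others. Differences between cultures that the replicate numbers do not record stay open as well.

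Weak calls (q of 0.05 or above) fell into the same autosomal segments in libraries of different antibodies. In 94 bins of 1 Mb, weak calls of 7 of the 24 other libraries followed those of control MSL3 replicate 3 more closely than the highest of 1000 shifts, 4 of 7 CLAMP, 1 of 8 GAF and 2 of 9 MSL3 libraries, and the first 7 Mb of 3L, 28.5% of the arm, held 77.1% of that library's weak calls on 3L. The closest profile was that of CLAMP replicate 2 under GAF RNAi (Spearman 0.745 across bins, highest shift 0.579; bins are not independent replicates), which held 74.1% of its weak 3L calls in the same 7 Mb. The 577 CLAMP sites gained under GAF RNAi had a Spearman coefficient of 0.614 with the profile of control MSL3 replicate 3, which is no separate support because they are calls of both GAF RNAi libraries whose weak calls already did so (0.539 and 0.745), and 199 of them (34.5%) lay in MSL3 regions, against 20.8% of the CLAMP sites called in every library of that comparison. MSL3 binding in these segments or segments over-represented in the DNA of these cells may account for it, and both stay open, since 7 of the 24 libraries passed, 1 of them a GAF library, and reads of inputs were not analysed here.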
